A study of Mus musculus with 6 samples.

How the data were processed

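Total RNA from mouse cardiac grafts was measured on 6 Affymetrix oligonucleotide arrays of a single design. Each array belonged to a group of its own, taken from the labels: untreated syngraft, untreated allograft, and allografts from mice given ABH4 (4-amino tetrahydrobiopterin), BH4 (tetrahydrobiopterin), CsA (cyclosporin A) or NIL (N-imino ethyl-L-lysine). The values deposited by the authors were a signal intensity for each of 22690 probe sets per array. The values were linear, and the mean of every array after trimming 2% from each end was 200 to 3 digits, so the arrays had already been scaled to a common level. The scanner software, summarisation method and background correction were not given in the sources used here. Whether RNA of several grafts was pooled on an array, the mouse strains and the day of removal were not given either.

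Each array was rescaled so that its median over the 22626 probe sets other than controls equalled the mean of the 6 medians. The rescaling moved the arrays by between -0.09 and 0.10 on the log2 scale. Signals below the 30th percentile of all rescaled values (34.8, or 5.12 on the log2 scale) were set to that floor, and log2 was taken. The floor also covered 3 deposited values at or below 0. Fold differences of genes at the floor on 1 of the compared arrays are lower bounds and are given as "at least". A gene took the value of its brightest probe set among those assigned to exactly 1 gene symbol, which gave 12393 genes from 20380 probe sets. The 691 probe sets listed for several genes and the 1555 without a gene entered no comparison. No genome positions were used, because the probe annotation names no genome build.

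Comparisons were allograft with syngraft, each of the 4 treated allografts with the untreated allograft, and ABH4 with BH4. With 1 array per group no variance could be estimated, so no test of significance was made and no p-value is given. Each comparison is described by log2 differences, by the number of genes at least 2-fold and at least 3-fold higher or lower, and by 27 gene lists for cell types and pathways. For each list the median log2 difference was set against 10000 random gene lists of the same size, drawn to match its members on mean signal in 20 bins. A list is called outside its random lists when its median lay below the 2.5th percentile or above the mirror percentile at the upper end. Such a percentile compares a list with other genes on the same arrays and says nothing of the spread between grafts. List members are counted as at least 1.5-fold higher, at least 1.5-fold lower, or between. Of the 415 list members, counted once per list, 368 had a probe set of their own, and the others were not analysed here. Some genes, such as Tap1, Tap2, Cxcl9 and C1qb, belong to more than 1 list, so the lists are not independent of each other.

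The comparisons, gene lists, floor, scaling and the rule for named genes were set before the data were examined. The rule named, per comparison, the 6 largest differences in each direction among genes above the floor on both arrays and above the array median on at least 1 of them. Genes whose other probe sets differed in sign were left out of that part. It also named the 3 largest lower bounds in each direction, the 2 members that moved most in each list outside its random lists, and Nos2, Gch1, Ifng, Gzmb, Cxcl9, Nppa and Myh6 throughout. Genes named beyond the rule are marked as chosen after their values were seen. A non-matrix fibroblast list and an epithelial and glandular list were added after seeing the data, and were not compared with random lists.

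The procedure was tested on simulated data that took their spread from the untreated allograft and ABH4 arrays. The noise was normal, independent between genes and set by a robust spread at each signal level, and the genes shifted by a fold lay above the median signal. A 2-fold threshold found 8.0% of genes shifted 1.5-fold, 52.0% of those shifted 2-fold, 98.0% of those shifted 3-fold and 0.189% of unshifted genes. Lists of 18 genes shifted by 0.30 were outside their random lists in 30 of 30 draws, against 1 of 30 unshifted lists. The SD of log2 differences across genes was 0.290 for ABH4 against untreated allograft. It was between 0.358 and 0.719 for the other comparisons. The simulated rates therefore do not carry over to those wider comparisons. For ABH4 too they describe an ideal case. The robust SD across genes was 0.179, below the SD of 0.290, and the ABH4 and untreated arrays themselves differed at least 2-fold in 119 of 12393 genes. The rate for lists leaves out genes that vary together. Correlation between treatments that share the untreated array was simulated with 100 draws of independent arrays. Alternatives were the deposited values without rescaling, quantile normalization, a floor at the 10th or the 50th percentile, the mean over all probe sets of a gene, and only genes above the floor on at least 1 compared array. A count without genes peculiar to the BH4 array was added after seeing the data. Calculations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots used matplotlib 3.10.9.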

Results

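Gene expression was measured in mouse hearts after transplantation, with 1 array for each of 6 groups. The syngraft came from a transplant without a donor-recipient difference and the untreated allograft from a transplant across one. The other 4 arrays came from allografts of treated mice. BH4, tetrahydrobiopterin, is the cofactor of the nitric oxide synthases, and ABH4 is its 4-amino analog and an antagonist of that cofactor. Both pteridines were given at 50 mg/kg every 8 h. NIL, an inhibitor of inducible nitric oxide synthase, was given at 5 mg/kg every 8 h. CsA, which blocks calcineurin and so T cell activation, was given at 15 mg/kg every 24 h. The median deposited signal was between 77.7 and 88.5 per array and the highest between 8819 and 10669. The 3' to 5' signal ratio, a measure of RNA integrity, was between 1.04 and 1.13 for Actb and between 0.788 and 0.876 for Gapdh. The number of arrays limits the precision: no replicate exists against which any difference below can be checked. Across genes, which are not independent replicates, Pearson's r between pairs of arrays lay between 0.916 and 0.987.

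The comparison of untreated allograft with syngraft sets a graft met by alloimmunity beside a graft that is not. The strains were not given and neither group had a replicate. Differences between strains or between single grafts therefore cannot be told apart from alloimmunity here. Transcripts of cytotoxic lymphocytes, T cells, antigen presentation and the interferon response were higher in the allograft, and transcripts of the extracellular matrix were lower. Gzmb, the protease of cytotoxic granules, had a signal of 3888 in the allograft and was at the floor in the syngraft, a difference of at least 112-fold. Ifng, the cytokine of activated T and NK cells, was at least 16.8-fold higher, and Cxcl9, a T cell chemoattractant that interferon-gamma induces, was 24.8-fold higher. Postn, a matrix protein of fibroblasts, had a signal of 219 in the allograft and 3142 in the syngraft, 14.3-fold lower.

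All 19 measured interferon-gamma induced genes were at least 1.5-fold higher in the allograft, with a median log2 difference of 3.42. They included Gbp2, a guanylate-binding protein of host defence (27.5-fold), and Cxcl11 (at least 26.6-fold). Of the cytotoxic lymphocyte genes 15 of 16 were higher (median 2.46, or 2.91 and 1.64 with floors at the 10th and the 50th percentile), among them Gzma (22.6-fold). T cell genes were higher in 14 of 18 (median 1.65, or 2.10 and 0.84 with the same floors), and the T cell receptor chains Cd3g and Cd3d were at least 14.7-fold and at least 14.2-fold higher. Antigen presentation genes were higher throughout: 7 of 7 MHC class I genes (median 1.88) and 8 of 8 MHC class II genes (median 1.72). H2-K1 was 16.2-fold and H2-D1 18.8-fold higher, although another probe set of H2-D1 differed in sign, and H2-DMa and H2-Ab1 were 6.71-fold and 3.92-fold higher. Of the type I interferon induced genes 13 of 14 were higher (median 2.27), led by Ifit2 (10.3-fold) and Ifit3 (9.46-fold).

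Chemokine and receptor genes were higher in 15 of 18 and lower in 2 (median 1.84), with Cxcl10 18.5-fold higher. Cytokine genes were higher in 9 of 17 and lower in 2 (median 1.14), with Ltb, which encodes lymphotoxin beta, 7.95-fold higher. Macrophage and monocyte genes were higher in 14 of 20 (median 1.15), including the integrin Itgb2 (6.25-fold) and the scavenger receptor Msr1 (5.80-fold). Oxidative and heat stress genes were higher in 10 of 15 (median 1.10), including the glutathione synthesis gene Gclm (8.13-fold) and the sulfiredoxin Srxn1 (5.12-fold). Complement genes were higher in 6 of 11 (median 0.60), with Cfb 9.63-fold and C1qc 2.13-fold higher. Gbp6 (36.7-fold), Gbp8 (at least 28.8-fold), the checkpoint ligand Cd274 (33.4-fold) and xanthine dehydrogenase Xdh (23.3-fold) were the other genes furthest above the syngraft.

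The extracellular matrix list was lower in 16 of 18 members and higher in 0, with a median of -1.98. Col6a1, a collagen VI chain, was 8.56-fold lower. Of 12 fibroblast genes that are not matrix proteins, a list added after seeing the data, 8 were lower and 0 higher (median -0.82). At the floor on the syngraft array were 2 of the 12, which could not be lower. Outside the list the furthest below the syngraft were the calcification inhibitor Mgp (21.3-fold), Abca8a (17.3-fold), the collagen Col8a1 (13.8-fold), the apelin receptor Aplnr (13.7-fold) and Pi16 (13.6-fold). Sparcl1, the growth factor Igf1 and Rcn3 were at the floor in the allograft and at least 21.2-fold, 13.9-fold and 11.4-fold lower. Endothelial genes were lower in 4 of 13 and higher in 2 (median -0.37), with Tek and Vwf 2.68-fold and 2.67-fold lower. Cardiomyocyte contractile genes were lower in 2 of 22 (median -0.13, or -0.31 on the deposited values and -0.18 after quantile normalization). These were headed by the muscle creatine kinase Ckm (3.65-fold) and the sarcomere spring Ttn (1.92-fold). Genes of oxidative phosphorylation and the citrate cycle all stayed within 1.5-fold (19 of 19, median -0.14, or -0.33 and -0.29 in the same order), with Cox7a1 1.44-fold and Ogdh 1.34-fold lower. The adipose list had a median of -0.08, which was 0.00 after quantile normalization and with a floor at the 50th percentile, with Fabp4 2.42-fold and Retn 1.27-fold lower.

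Nos2, inducible nitric oxide synthase, had a signal of 73.2 in the allograft and was at the floor in the syngraft, at least 2.10-fold. Gch1, the rate-limiting enzyme of tetrahydrobiopterin synthesis, was 2.81-fold higher. The signals of Nppa, atrial natriuretic peptide, were 8594 and 9483, close to the highest on an array (8819 to 10669 as deposited). Whether differences of Nppa are compressed there was not tested, here or in the comparisons below. The signals of Myh6, the adult atrial and ventricular myosin of the mouse, were 3578 and 3341, and its sign reversed from 0.10 to -0.09 on the deposited values. Medians of the other lists lay within their random lists: nitric oxide, pteridine and arginine metabolism 0.09, neutrophil -0.25, B cell and plasma cell -0.37, cell cycle 0.34, cardiac stress -0.02 and housekeeping 0.19. So did those of skeletal muscle (0.00), erythroid (0.00, or -0.16 as deposited), calcineurin and NFAT (0.00, or -0.05 as deposited), dendritic cell (0.02, or -0.06 as deposited) and fatty acid oxidation (0.14, or -0.05 as deposited).

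In all, 849 of 12393 genes were at least 2-fold higher and 592 lower in the allograft, and 339 and 198 at least 3-fold. The median of all genes differed by -0.19 in the deposited values, which the rescaling removed, and without it 629 genes were higher and 859 lower. A floor at the 10th percentile gave 1283 higher and 1374 lower genes, and at the 50th percentile 292 were lower. Of the 27 lists, 16 were outside their random lists.

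**Figure D1:**
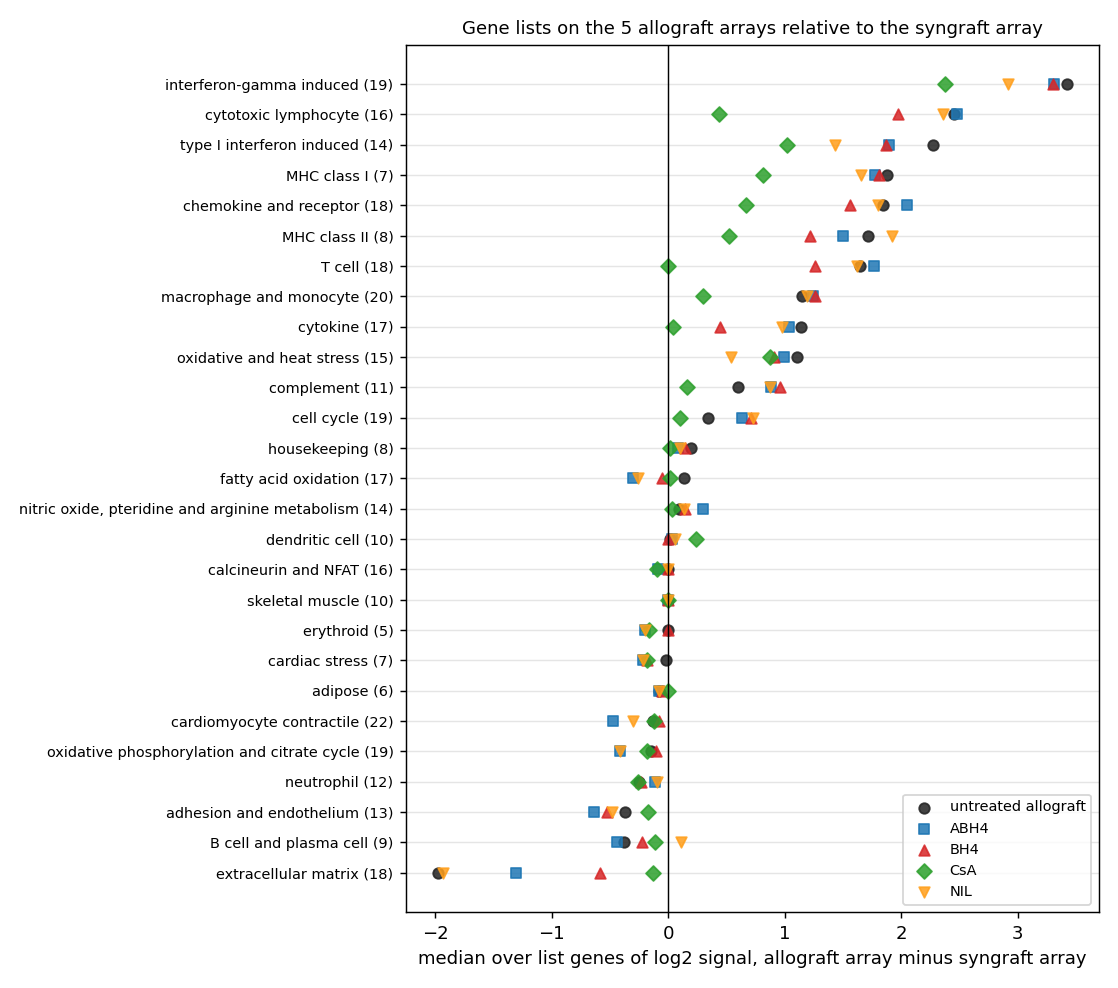
Median log2 signal of each of the 27 gene lists on the 5 allograft arrays minus the syngraft array; each marker is 1 array and the number of measured genes stands in brackets. The extracellular matrix list lies at -1.98 for the untreated allograft and at -1.30, -0.59, -0.13 and -1.93 for ABH4, BH4, CsA and NIL.

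The CsA comparison shows how the allograft profile under calcineurin inhibition differed from that without treatment. Lymphocyte transcripts were lower and matrix transcripts higher than in the untreated allograft, and interferon-induced transcripts were lower but stayed well above the syngraft. Gzma and Gzmb were 13.7-fold and 11.2-fold lower, and the T cell receptor chains Cd3d and Cd3e were at the floor, with Cd3d at least 14.2-fold lower. Postn and Mgp were 13.8-fold and 14.8-fold higher. The CsA array had the profile nearest to the syngraft: r was 0.965 across genes, against 0.916 for the untreated allograft.

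T cell genes were lower with CsA in 16 of 18 (median -1.49) and cytotoxic lymphocyte genes in 15 of 16 (median -1.72). Against the syngraft, the T cell median was 0.00 and the cytotoxic median 0.44, or 0.81 and 0.019 with floors at the 10th and the 50th percentile. Interferon-gamma induced genes were lower in 16 of 19 (median -0.95), with the immunoproteasome subunits Psmb8 and Psmb9 3.62-fold and 3.48-fold lower, yet their median stood 2.38 above the syngraft. Cxcl9 was 1.58-fold lower, with a signal of 2498, and Ifng 5.72-fold lower. Type I interferon induced genes were lower in 12 of 14 (median -0.81), with Ifi35 2.71-fold and Rsad2 2.15-fold lower. MHC class I genes were lower in 6 of 7 (median -0.81), with the peptide transporters Tap2 and Tap1 2.78-fold and 2.02-fold lower. MHC class II genes were lower in 7 of 8 (median -1.18), with H2-DMa 3.27-fold and H2-Ab1 2.74-fold lower. Macrophage and monocyte genes were lower in 13 of 20 (median -0.79), with Msr1 5.02-fold and Itgb2 4.16-fold lower. Chemokine and receptor genes were lower in 11 of 18 and higher in 2 (median -0.83), and cytokine genes were lower in 8 of 17 (median -0.42, or 0.00 with a floor at the 50th percentile). Among them Ccl3 was 12.4-fold, Xcl1 5.64-fold and Ltb at least 10.3-fold lower. Saa3, an acute-phase protein, was 20.6-fold lower, and the lymphocyte genes Ms4a4b and Nkg7 were 9.24-fold and 9.20-fold lower.

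Extracellular matrix genes were higher with CsA in 15 of 18 and lower in 0 (median 1.82), with Col6a1 7.72-fold higher. Of the 12 non-matrix fibroblast genes 7 were higher and 0 lower (median 0.93). Abca8a (10.2-fold), Col8a1 (9.96-fold), Lum (9.43-fold) and Dpt (9.11-fold), and Igf1, Sparcl1 and the growth factor Ptn (at least 13.6-fold, 10.8-fold and 10.6-fold), were also higher. Endothelial genes were higher in 4 of 13 and lower in 1 (median 0.25, or 0.00 with a floor at the 50th percentile), with Tek 2.31-fold and Vwf 2.26-fold higher. Cardiomyocyte contractile genes were higher in 1 of 22 and lower in 0, with Ckm 2.71-fold and Ttn 1.39-fold higher. Their median was 0.06, where their random lists had -0.18 (0.25 for the list on the deposited values and 0.21 after quantile normalization). Oxidative phosphorylation genes were higher in 0 of 19 and lower in 1. Their median was 0.01, where their random lists had -0.21 (0.20 and 0.19 for the list in the same order). Cox7a1 was 1.16-fold higher and Ndufv1 1.20-fold higher, although another probe set of Ndufv1 differed in sign. Nos2 was at the floor with CsA, at least 2.10-fold lower, and Gch1 was 1.51-fold lower, with another probe set of opposite sign. Nppa had signals of 8360.3 and 8594, and its sign turned from -0.04 to 0.15 on the deposited values. Myh6 was 1.21-fold higher, with another probe set of opposite sign.

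With CsA 396 genes were at least 2-fold higher and 497 lower, and 125 and 135 at least 3-fold. Of the 27 lists 13 were outside their random lists. The calcineurin and NFAT list was within them, with 3 of 16 genes lower and 0 higher (median -0.05, or 0.04 on the deposited values). So was nitric oxide, pteridine and arginine metabolism, with 3 of 14 lower and 2 higher (median -0.19). The deposited medians differed by 0.19, and without rescaling 594 genes were higher and 323 lower. Floors at the 10th and the 50th percentile gave 1087 and 181 higher genes, and 889 and 339 lower genes.

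The BH4 comparison shows how the allograft profile under the natural cofactor differed from that without treatment. Matrix genes were higher and lymphocyte genes modestly lower than in the untreated allograft, while interferon-gamma induced genes stayed close to it. Postn was 7.36-fold and the collagen Col1a1 5.70-fold higher, Sfrp2 5.87-fold higher, and the collagen-degrading protease Ctsk 6.01-fold higher. Extracellular matrix genes were higher in 15 of 18 and lower in 0 (median 1.43). Of the 12 non-matrix fibroblast genes 6 were higher and 0 lower (median 0.31). The BH4 array also carried transcripts of salivary secretions far above the other arrays: Bpifa2 had a signal of 5806, at least 167-fold above the untreated allograft. Smr3a (at least 91.1-fold), 2310057J18Rik (at least 85.2-fold), Wfdc18 (15.1-fold) and lactoferrin, Ltf (6.50-fold), were higher with it. On the BH4 array 26 genes were at least 2-fold above every other array, against 49 on the syngraft, 5 on CsA, 3 on NIL, 2 on ABH4 and 2 on the untreated allograft.

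Cytotoxic lymphocyte genes were lower with BH4 in 6 of 16 (median -0.46), with Xcl1 2.16-fold and Gzmc 1.79-fold lower. T cell genes were lower in 3 of 18 (median -0.38), with Cd2 2.09-fold and Cd247 1.84-fold lower, and Slamf6, a lymphocyte receptor, was 2.55-fold lower. All 8 MHC class II genes stayed within 1.5-fold (median -0.46), with the master regulator Ciita and H2-Eb1 each 1.49-fold lower. Type I interferon induced genes were lower in 3 of 14 (median -0.22), with Mx1 1.75-fold and Mx2 at least 2.20-fold lower. Macrophage genes had a median of 0.20 with 1 of 20 higher: lysozyme Lyz2 was 1.41-fold higher and C1qb 1.52-fold higher, although another probe set of C1qb differed in sign. Gpnmb, a glycoprotein of phagocytes, was 12.3-fold higher. Complement genes were higher in 4 of 11 (median 0.21), with C2 1.71-fold and C1s1 1.70-fold higher. The 5 erythroid genes stayed within 1.5-fold (median 0.38, or 0.00 with a floor at the 50th percentile), with Alas2 1.45-fold and Slc4a1 1.32-fold higher.

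Interferon-gamma induced genes had a median of -0.07 with BH4 and 1 of 19 was lower. Ifng was 1.46-fold, Gzmb 1.31-fold and Nos2 1.34-fold lower. The signals with and without BH4 were 256 and 279 for Gch1, where another probe set differed in sign, 3928 and 3938 for Cxcl9, 8369.9 and 8594 for Nppa and 3236 and 3578 for Myh6. Furthest below the untreated allograft were the kinase Stk10 (3.97-fold), Ly6i (3.61-fold), Fbxo11 (2.65-fold), Asb5 (2.62-fold) and Mlst8 (2.52-fold). Map11, Med17 and Ptpn23 were at the floor and at least 3.90-fold, 3.55-fold and 2.80-fold lower.

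With BH4 191 genes were at least 2-fold higher and 51 lower, and 78 and 4 at least 3-fold. Of the 27 lists 8 were outside their random lists. Nitric oxide, pteridine and arginine metabolism was within them (median 0.04), with all 14 genes within 1.5-fold. Without the 26 genes peculiar to the BH4 array, a count chosen after seeing the data, 165 were higher and 51 lower. Floors at the 10th and the 50th percentile gave 710 and 95 higher genes, and 493 and 12 lower genes.

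The ABH4 comparison shows the same for the 4-amino analog. Lymphocyte and interferon-gamma induced genes stayed close to the untreated allograft, matrix genes were higher, and fatty acid oxidation genes were lower. Igk and Jchain, which belong to secreted immunoglobulin, were 5.45-fold and 3.44-fold higher, but the B cell and plasma cell list was not outside its random lists (median 0.00, 3 of 9 higher). The type I collagen chain Col1a2 and Postn were 2.36-fold and 2.31-fold higher. The ABH4 and untreated allograft arrays were the closest of the 15 pairs, with r of 0.987 across genes.

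Extracellular matrix genes were higher with ABH4 in 10 of 18 and lower in 0 (median 0.64), while of the 12 non-matrix fibroblast genes 1 was higher and 2 were lower (median 0.066). Complement genes were higher in 3 of 11 (median 0.28), with C1s1 2.11-fold and C2 1.63-fold higher. Cell cycle genes were higher in 1 of 19 (median 0.27): the replication helicase subunit Mcm2 was 1.82-fold higher, and Tk1 1.39-fold. Nitric oxide, pteridine and arginine metabolism genes were higher in 2 of 14 (median 0.15, or 0.00 with a floor at the 50th percentile), namely the arginine transporter Slc7a2 (2.48-fold) and the arginase Arg2 (1.56-fold). Chemokine genes had a median of 0.10 with 1 of 18 higher, Cxcl1 (1.95-fold), and Ccl7 was 1.35-fold higher. All 20 macrophage genes stayed within 1.5-fold (median 0.07), with C1qb 1.37-fold and Mpeg1 1.28-fold higher. Fatty acid oxidation genes were lower in 4 of 17 and higher in 0 (median -0.43), including their regulator Ppara (2.07-fold) and Cpt2 (1.65-fold). Oxidative phosphorylation genes were lower in 1 of 19 (median -0.28), Cyc1 (1.57-fold), and Uqcrc1 was 1.39-fold lower. All 22 cardiomyocyte contractile genes stayed within 1.5-fold (median -0.26), with Ldb3 1.45-fold and Tnni3 1.41-fold lower. Type I interferon induced genes were lower in 2 of 14 (median -0.25): Mx2 was at least 2.20-fold and Rsad2 1.51-fold lower.

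The T cell median was 0.10, the cytotoxic median 0.07 and the interferon-gamma median -0.13 with ABH4, all within their random lists. Nos2 was 1.19-fold lower and Ifng 1.26-fold higher. The signals with and without ABH4 were 263 and 279 for Gch1, with another probe set of opposite sign, and 3703 and 3888 for Gzmb, where the sign turned after quantile normalization from -0.07 to 0.02. They were 4265 and 3938 for Cxcl9, 7143 and 8594 for Nppa and 3161 and 3578 for Myh6. The alarmin Il33 (4.69-fold), Iglv1 (3.80-fold), the Wnt antagonist Sfrp1 (3.76-fold), Hoxa9 (3.42-fold), Igkv15-103 (at least 4.06-fold) and S1pr3 (at least 3.15-fold) were higher. Wdr36 was at least 3.81-fold higher, with another probe set of opposite sign. Vmn1r44 (4.11-fold), Ankrd2 (2.87-fold), Mpg (2.85-fold), Gga1 (2.80-fold), Sox10 (2.74-fold) and Fbxo28 (signals 55.0 and 137) were lower. Gdpd5, Foxf1 and Ptpn23 were at the floor and at least 3.04-fold, 2.95-fold and 2.80-fold lower.

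With ABH4 84 genes were at least 2-fold higher and 35 lower, and 15 and 2 at least 3-fold. Of the 27 lists 10 were outside their random lists. Floors at the 10th and the 50th percentile gave 531 and 31 higher genes, and 437 and 3 lower genes.

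ABH4 and BH4 differ by the amino group at position 4 of the pterin ring and were given at the same dose and interval, so their arrays were compared directly. Lymphocyte genes were higher with ABH4 and matrix genes higher with BH4. The granule protease Gzma was 1.81-fold and the NK receptor Klrd1 1.98-fold higher with ABH4, and Postn and Col5a2 were 3.19-fold and 2.64-fold lower. Cytotoxic lymphocyte genes were higher with ABH4 in 8 of 16 (median 0.65) and T cell genes in 6 of 18 (median 0.53), including Cd2 (2.05-fold) and Cd247 (1.73-fold). Cytokine genes were higher in 5 of 17 (median 0.31, or 0.00 with a floor at the 50th percentile), with Il6 2.33-fold and Ifng 1.84-fold higher. Chemokine genes were higher in 6 of 18 (median 0.24), with Ccl3 2.64-fold and Cxcl1 1.91-fold higher. MHC class II genes had a median of 0.28, with H2-DMb2 1.33-fold and H2-Ab1 1.32-fold higher, and cell cycle genes a median of 0.25, with Mcm2 1.64-fold and Mcm6 1.46-fold higher.

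Extracellular matrix genes were lower with ABH4 than with BH4 in 12 of 18 and higher in 0 (median -0.83), and so were 6 of the 12 non-matrix fibroblast genes (median -0.55). Fatty acid oxidation genes were lower in 2 of 17 (median -0.33), with Ppara 1.63-fold and Acaa2 1.52-fold lower. Oxidative phosphorylation genes were lower in 1 of 19 (median -0.28), with Cyc1 1.74-fold and Idh3a 1.30-fold lower. Cardiomyocyte contractile genes were lower in 2 of 22 (median -0.24), with Ckm at 370.0 against 739 and Casq2 1.56-fold lower. The salivary products Bpifa2, Smr3a and Dnase1 were at the floor with ABH4, at least 167-fold, 91.1-fold and 79.4-fold below BH4. Also lower were 2310057J18Rik (60.5-fold), Wfdc18 (103 against 1230.0), Dcpp3 (6.60-fold), Ltf (5.30-fold), Gpnmb (4.97-fold) and the tight junction gene Cldn3 (4.33-fold). Igk was 6.62-fold, Jchain 3.89-fold, Igha 3.03-fold and Igkv15-103 at least 4.06-fold higher with ABH4, while the B cell and plasma cell list was not outside its random lists (median 0.02, 2 of 9 higher). Ly6i (3.40-fold), Hoxa9 (2.86-fold), Stk10 (2.65-fold), Map11 (at least 3.76-fold) and Med17 (at least 3.71-fold) were higher too.

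The pteridines did not differ by 1.5-fold in Nos2 (signals 61.3 with ABH4 and 54.7 with BH4), Gch1 (263 and 256), Gzmb (3703 and 2973) or Cxcl9 (4265 and 3928). Nor did they in Nppa (7143 and 8369.9) or Myh6 (3161 and 3236), whose signs both turned after quantile normalization, to 0.02 and 0.09. Interferon-gamma induced genes had a median difference of 0.00 with 1 of 19 higher, and MHC class I genes a median of -0.12 with 0 of 7 beyond 1.5-fold. Macrophage genes had a median of -0.01 with 0 of 20 beyond 1.5-fold, and 0.02 on the deposited values. With 1 array each no interval for these differences can be given, so that likeness is not shown. In all, 56 genes were at least 2-fold higher and 119 lower with ABH4, 9 and 34 at least 3-fold, and 93 were lower without the 26 genes peculiar to the BH4 array. Of the 27 lists 10 were outside their random lists, and floors at the 10th and the 50th percentile gave 489 and 14 higher and 578 and 46 lower genes.

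**Figure D2:**
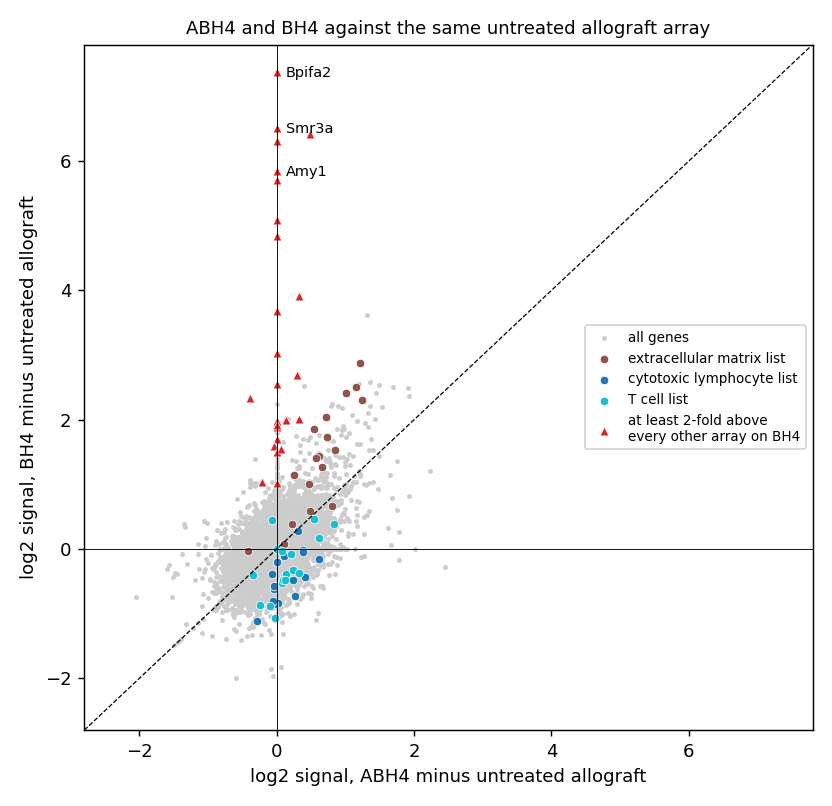
Log2 signal of ABH4 minus untreated allograft (horizontal) against BH4 minus untreated allograft (vertical), 1 point per gene, with 3 gene lists and the 26 genes at least 2-fold above every other array on BH4 marked; the dashed line is equality. Bpifa2 lies at 7.38 on the vertical axis, and the matrix list has medians of 0.64 with ABH4 and 1.43 with BH4.

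The NIL comparison shows the difference under inhibition of inducible nitric oxide synthase. Stress genes were lower than in the untreated allograft, and so were type I interferon genes, as on every treated array. Of the B cell and plasma cell genes 3 of 9 were higher, and matrix genes stayed close to the untreated allograft. Srxn1 was 2.26-fold lower, with another probe set of opposite sign, and the heat shock gene Hspa1a was 2.02-fold lower. Igk was 4.99-fold and Jchain 3.09-fold higher. The dose of NIL was lower than that of the pteridines, and CsA was given at another interval.

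Oxidative and heat stress genes were lower with NIL in 8 of 15 and higher in 0 (median -0.59, where their random lists had -0.19). Type I interferon induced genes were lower in 8 of 14 and higher in 0 (median -0.60, where their random lists had -0.16), with Rsad2 2.53-fold and Mx2 at least 2.20-fold lower. The stress median was -0.45 on the deposited values and -0.42 after quantile normalization, and the type I interferon median -0.46 and -0.41. Those medians lay within 1.5-fold, the cut behind these counts. Fatty acid oxidation genes were lower in 3 of 17 (median -0.34, where their random lists had -0.17). Slc25a20 and Cpt2 were 1.61-fold lower, the latter with another probe set of opposite sign. The list median was -0.19 on the deposited values, where differences are higher by about 0.15, and -0.16 after quantile normalization. Random lists were drawn on the rescaled arrays only. All 19 oxidative phosphorylation genes stayed within 1.5-fold (median -0.28, where their random lists had -0.20), with Uqcrc1 1.42-fold and Cox7a1 1.38-fold lower. Under the same 2 alternatives, without random lists of their own, the list median was -0.13 and -0.087. B cell and plasma cell genes were higher in 3 of 9 (median 0.54, or 0.00 with a floor at the 50th percentile), with Cd22 2.32-fold higher. T cell genes were higher in 2 of 18 (median 0.17), with Cd6 1.92-fold and Cd8a 1.55-fold higher. Cytotoxic genes were higher in 2 of 16 (median 0.19), with Gzmk 1.72-fold higher and Klrc1 1.54-fold higher, the latter with another probe set of opposite sign.

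Several lists were outside their random lists with NIL although nearly all members stayed within 1.5-fold. For the extracellular matrix list the random lists had a median of -0.19, and for the cell cycle list -0.081, both on the rescaled arrays. All 18 extracellular matrix genes stayed within 1.5-fold (median 0.03), with Timp1 1.33-fold and Col5a1 1.26-fold higher, the latter with another probe set of opposite sign. All 8 MHC class II genes (median 0.13) included H2-Oa at 1.44-fold and H2-Eb1 at 1.15-fold higher. Of 20 macrophage genes 1 was higher, Cd14 (1.61-fold), and the median was 0.09, with Mpeg1 1.28-fold higher. All 11 complement genes (median 0.01) included Cfp at 1.44-fold and C1qb at 1.28-fold higher. Of 19 cell cycle genes 1 was higher, Mcm2 (1.67-fold, with another probe set of opposite sign), and the median was 0.15, with Aurka 1.31-fold higher. On the deposited values these 5 medians were 0.18 (matrix), 0.28 (MHC class II), 0.24 (macrophage), 0.16 (complement) and 0.30 (cell cycle), and after quantile normalization 0.19, 0.29, 0.28, 0.17 and 0.24.

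Nos2, whose enzyme NIL inhibits, was 1.20-fold higher with NIL, and Ifng was 1.21-fold and Gzmb 1.16-fold lower. The signals with and without NIL were 249 and 279 for Gch1, with another probe set of opposite sign. On the deposited values the signs turned for Cxcl9 (3712 and 3938, from -0.09 to 0.06), Nppa (8001 and 8594, from -0.10 to 0.04) and Myh6 (3363 and 3578, from -0.09 to 0.06). Gpnmb (3.53-fold), Hoxa9 (3.48-fold), Atp7b (3.35-fold), Iglv1 (3.20-fold), the amino acid oxidase Il4i1 (3.17-fold), Creb3l3 (at least 4.01-fold) and Igkv6-14 (at least 3.65-fold) were higher. Wdr36 was at least 5.45-fold higher and Spata5 at least 3.89-fold lower, each with another probe set of opposite sign. Zdhhc12 (4.31-fold), Clpx (3.19-fold), Tcim (2.76-fold), Mark4 (2.73-fold), Bmyc (2.68-fold), the glutathione peroxidase Gpx3 (2.63-fold), Zdhhc6 (at least 5.67-fold) and Prkrip1 (at least 3.95-fold) were lower.

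With NIL 162 genes were at least 2-fold higher and 98 lower, and 18 and 8 at least 3-fold. Of the 27 lists 12 were outside their random lists. Nitric oxide, pteridine and arginine metabolism was within them (median 0.19), with 3 of 14 genes higher and 1 lower. The deposited medians differed by 0.15, and without rescaling 266 genes were higher and 53 lower. Floors at the 10th and the 50th percentile gave 870 and 18 higher genes, and 485 and 29 lower genes.

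Seen from the syngraft, matrix genes separated the treatments. The extracellular matrix median lay at -1.98 on the untreated allograft array, -1.93 with NIL, -1.30 with ABH4, -0.59 with BH4, the array that carried the salivary transcripts, and -0.13 with CsA. With the mean over all probe sets of a gene the NIL median was -2.17, below that of the untreated allograft. The cytotoxic median lay at 2.46, 2.36, 2.48, 1.98 and 0.44 in the same order, and the interferon-gamma median at 3.42, 2.92, 3.31, 3.30 and 2.38. The cytotoxic order depends on the floor: the medians were 2.91, 3.04, 2.86, 2.34 and 0.81 with a floor at the 10th percentile and 1.64, 2.05, 1.86, 1.18 and 0.019 at the 50th, so that NIL lay above the untreated allograft, as it also did on the deposited values (2.37 against 2.31). Over all genes, the root mean square difference from the syngraft was 97.6% of that of the untreated allograft with ABH4, 94.9% with NIL, 91.3% with BH4 and 61.2% with CsA. After quantile normalization ABH4 (99.4%) and NIL (99.5%) were level.

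The 4 treated arrays share 1 untreated array, so its own deviations enter every treatment difference. Type I interferon induced genes were lower and outside their random lists with all 4 treatments (medians -0.25 with ABH4, -0.22 with BH4, -0.81 with CsA and -0.60 with NIL). For this list a high level on the untreated array cannot be told apart from effects of the treatments. Over the 6 pairs of treatments, the differences correlated across genes at r between 0.34 and 0.50, where unrelated arrays with a shared control gave 0.50 in simulation. The covariances lay between 0.0521, for ABH4 with BH4, and 0.109, for BH4 with CsA, all above the simulated 0.0404. BH4 and CsA had 121 genes at least 2-fold higher in both, and ABH4 and BH4 had 48. Independent sets of these sizes would share 6.10 and 1.29, and the simulated arrays with a shared control shared 2.12. The simulation took its spread from the ABH4 and untreated arrays, whose differences had an SD of 0.290 across genes. The SD was 0.385 with BH4, 0.566 with CsA and 0.376 with NIL. The simulated covariance and shared count are therefore not expected values for these wider differences. With a single untreated array the control could not be split, so how much of the sharing comes from it cannot be told.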

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

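The tests of dilution, of scaling, of neutrophils and of the salivary products were chosen only after the results they bear on had been seen.

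Outside the comparisons, 124 of the 2246 probe sets that are listed for several genes or for none were at least 2-fold higher on the untreated allograft than on the syngraft array, and 70 were at least 2-fold lower. They were singled out because no comparison used them. The furthest above the syngraft, each listed for several genes and so not named, had log2 differences of 4.51, 4.09 and 3.78.

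Extracellular matrix genes were lower on the untreated allograft than on the syngraft array, with a median of -1.98 over 18 genes. Scaling is argued against as the source, since the median was -2.16 on the deposited values and -2.18 after quantile normalization. Dilution of graft RNA by RNA of infiltrating cells would lower all graft genes alike. In contrast, 23 muscle genes below the top of the scale had a median of 0.060, with a robust SD of 0.508 between genes. They were selected by a syngraft log2 signal under 11, which favours a higher difference, and include fatty acid oxidation genes. The whole cardiomyocyte contractile, oxidative phosphorylation and fatty acid oxidation lists had medians of -0.13, -0.14 and 0.14. Fewer fibroblasts, or less connective tissue in the sampled piece, may have contributed and cannot be told apart from lower expression per cell. The 12 fibroblast genes that are not matrix proteins had a median of -0.82, between the bounds set for either reading, with 8 of 12 at least 1.5-fold lower. However, 2 of the 12 were at the floor on the syngraft array and could not be lower, and 5 were at the floor in the allograft. The median can therefore understate the decrease, and it cannot decide between the readings. Pdgfra, at the floor in the allograft, was at least 8.91-fold lower, Tcf21, Cd248 and Fap were at the floor there too, Osr1 was at the floor on both arrays, and Axl stood at 0.17.

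The BH4 array held 26 genes at least 2-fold above every other array, and 9 of the 26 were at least 8-fold above. Furthest above the highest other array were the salivary products Bpifa2 (103-fold), Smr3a (91.1-fold), Dnase1 (79.4-fold) and Amy1 (57.8-fold). Wdr46 (3.68-fold), Ggh (3.04-fold) and Rrp9 (2.06-fold) were also among the 26. Neutrophils, which also make lactoferrin, are argued against as the source of the 26 genes, whose median difference from the untreated allograft was 2.45. That median is raised by the selection of these genes for high signals on the BH4 array. The 9 genes of the neutrophil list above the floor on either array had a median of 0.089 with a robust SD of 0.923, and S100a8 and S100a9 stood at 0.09 and -0.21. Of all 12, however, 4 were higher (Ltf, itself among the 26, Mmp8, Lcn2 and Mmp9) and 1 lower (Csf3r), so that a smaller difference in neutrophils stays open. Salivary gland RNA is a candidate explanation that stays open: Bpifa2 (signal 5806), Amy1 (2011) and Klk1 were each at least 1.99 (log2) above the highest other array, but they are among the 26 genes, so this cannot decide it. A wider epithelial and glandular list, of which 14 of 19 genes were above the floor on some array, had a median of 0.84, short of the bound of 1 set beforehand, with 12 of the 14 highest on the BH4 array, but 6 of these are among the 26 genes and the other 8 of the 14 had a median of 0.24, with Epcam at 56.5 and Cdh1 and Krt19 at the floor, so the amount of epithelium stays open. Whether such RNA also carried matrix transcripts onto the BH4 array was not tested, nor was an effect of the BH4 treatment itself.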

How the results depend on the processing

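The counts without genes peculiar to the BH4 array were chosen only after the data had been seen; the other alternatives were planned. No list outside its random lists and no named gene at least 2-fold different reversed its direction under any alternative, although some medians came to 0.00. That held for adipose genes of allograft against syngraft after quantile normalization. It held with the floor at the 50th percentile for those genes, for nitric oxide, pteridine and arginine metabolism with ABH4, erythroid genes with BH4, cytokine and endothelial genes with CsA, B cell and plasma cell genes with NIL, and cytokine genes of ABH4 against BH4. Of the counts of genes at a threshold 27 moved and 49 stayed within 1.5 times; with the floor at the 10th percentile all 12 moved and at the 50th 10 of 12, so signals near background decide many 2-fold differences. Counting only genes above the floor on at least 1 array cannot alter a count, since genes at the floor on both arrays differ by 0. Its 12 counts are therefore among the 49 by construction. Of the list medians, 779 values stayed within the spread of random lists and 273 moved. Of the named genes, 1134 stayed within the spread of all genes and 206 moved. On the deposited values all 268 stayed, because that alternative shifts genes by less than this spread. Quantile normalization kept all 12 counts within 1.5 times. Without the genes peculiar to the BH4 array, 165 genes were higher and 51 lower with BH4 than without treatment. Except where the construction of an alternative shows it, the cause was not tested.

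With the floor at the 10th percentile, the genes higher and lower numbered 1283 and 1374 for allograft against syngraft. Against the untreated allograft they numbered 531 and 437 with ABH4, 710 and 493 with BH4, 1087 and 889 with CsA, and 870 and 485 with NIL, and for ABH4 against BH4 489 and 578. The T cell and cytotoxic medians were 2.10 and 2.91 for allograft against syngraft and -1.83 and -1.95 for CsA against the untreated allograft. Against the syngraft, T cell medians were 2.54 with ABH4, 1.83 with BH4 and 2.36 with NIL, and cytotoxic medians 2.86, 2.34, 0.81 and 3.04 with ABH4, BH4, CsA and NIL. The interferon-gamma median with NIL was 3.26. The distance from the syngraft was 94.2% with BH4, 72.7% with CsA and 95.9% with NIL.

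With the floor at the 50th percentile, 292 genes were lower for allograft against syngraft. Against the untreated allograft 31 genes were higher and 3 lower with ABH4, 95 and 12 with BH4, 18 and 29 with NIL, and 181 higher with CsA, and for ABH4 against BH4 the counts were 14 and 46. The medians for allograft against syngraft were 0.84 (T cell), 1.64 (cytotoxic) and 3.10 (interferon-gamma), those for CsA against the untreated allograft -0.84 and -1.51 (T cell and cytotoxic), and that for ABH4 against BH4 0.49 (cytotoxic). Against the syngraft, T cell medians were 0.93 with ABH4, 0.57 with BH4 and 0.98 with NIL, cytotoxic medians 1.86, 1.18, 0.019 and 2.05 with ABH4, BH4, CsA and NIL, and interferon-gamma medians 2.98, 2.92 and 1.80 with ABH4, BH4 and CsA. The distance with CsA was 57.1%.

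On the values as deposited, 323 genes were lower with CsA than without treatment, and 266 higher and 53 lower with NIL. Medians for allograft against syngraft were 1.46 (T cell), 3.24 (interferon-gamma) and -2.16 (matrix), and for CsA against the untreated allograft -1.31, -0.76 and 2.01. For NIL they were 0.32 (T cell), 0.34 (cytotoxic), -0.068 (interferon-gamma) and 0.18 (matrix). For BH4 against the syngraft they were 3.13 (interferon-gamma) and -0.76 (matrix).

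After quantile normalization, interferon-gamma and matrix medians were 3.25 and -2.18 for allograft against syngraft. Against the untreated allograft they were -0.024 and 0.71 with ABH4, -0.76 and 2.07 with CsA, and -0.039 and 0.19 with NIL. The interferon-gamma median for BH4 against the syngraft was 3.09. Distances were 99.4% with ABH4, 64.5% with CsA and 99.5% with NIL, so that ABH4 and NIL were level.

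With the mean over all probe sets of a gene, 33 genes were lower with BH4 than without treatment and 37 higher with ABH4 than with BH4. The matrix medians were 1.95 for CsA against the untreated allograft, -0.89 for ABH4 against BH4 and -2.17 for NIL against the syngraft, and the cytotoxic median for ABH4 against BH4 was 0.47. Interferon-gamma medians against the syngraft were 3.10 without treatment, 2.98 with ABH4, 2.96 with BH4 and 1.80 with CsA.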

Other observations

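All genes named in this part were chosen after their values were seen, except where the rule for named genes had already named them; the test below was narrowed to genes above the floor after its result over all 29 genes had been seen.

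A few immunoglobulin transcripts, picked for their values, differed between the treated arrays. The signal of Igha, the heavy chain of immunoglobulin A, was 454 on the syngraft array, 1810 on the untreated allograft and 1890.4 on the BH4 array, but 5725 with ABH4, 4199 with NIL and 3700.1 with CsA. Jchain, which joins the chains of secreted immunoglobulin, followed with 225, 534 and 473 against 1840.2, 1649 and 1313. Igk had 263 with ABH4, 241 with NIL and 134 with CsA, and 48.2 and 39.7 on the untreated allograft and BH4 arrays. The B cell and plasma cell list had a median against the untreated allograft of 0.54 with NIL, outside its random lists, and of 0.00 with ABH4, 0.00 with BH4 and 0.19 with CsA, within them. The B cell genes Ms4a1 and Cd79a had signals of at most 64.6 and 64.4 on any array.

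On the CsA array interferon-gamma induced genes were lower than on the untreated allograft array in 16 of 19 (median -0.95). Their median was still 2.38 above the syngraft. Cxcl10, a chemoattractant of T cells, had a signal of 1284 with CsA and 1442 without, against 77.9 in the syngraft, while Ccl3 had 43.5 with CsA and 538 without, against 35.5 in the syngraft. The heat shock gene Hspa1b had 1168 with CsA, 756 on the untreated allograft and 396 with NIL. The acute-phase gene Hp had 104 with CsA, below the syngraft with 1007 and the untreated allograft with 417. Arg1, the arginase of alternatively activated macrophages, was at the floor in the syngraft and had 864 on the untreated allograft, 324 with CsA and between 1009 and 1094 on the other treated arrays.

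In 29 genes the signal was lower by a like amount on all 5 allograft arrays, but 20 of them were at the floor on at least 1 of these arrays, 9 on all 5, where the floor makes the amounts alike. Of the other 9, Baiap2l1 was 13.5-fold and the skeletal actin Acta1 3.83-fold below the syngraft. Such a step may come from a sequence variant, an isoform or cross-hybridisation under a single probe set, which would leave the other probe sets of the gene in place. Over 10 other probe sets of 6 of these 9 genes, the median difference was 48.5% of that of the named probe set, between the bounds set for either reading, and over the 13 of all 29 genes it was 34.9%. The other probe set of Baiap2l1 showed 99.4% of the difference, those of Pdxdc1 -11.2% and 0.433%, so the genes do not share a single behaviour. Whether a strain difference between syngraft and allografts lowered any of these genes was not tested, since the strains were not given.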
